A study of Sus scrofa with 18 samples.

How the data were processed

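Messenger RNA levels were measured by RNA sequencing in 18 libraries of alveolar macrophages, the resident phagocytes of the lung airspaces, taken from healthy Danish Landrace-Yorkshire pigs and handled ex vivo. Per the labels, total RNA was taken up with mRNAeasy kits (Qiagen) and sequenced on an Illumina instrument. Per the labels, the cells were held in culture and exposed for 24 hours to 1 of 6 treatments, and each treatment has 3 libraries from pigs numbered 1 to 3. The treatments were no addition (control), poly I:C, Bacillus subtilis, Enterococcus faecium, and poly I:C together with either bacterium. Poly I:C is a synthetic double-stranded RNA used in place of a viral infection, and both bacteria are gram-positive species used as probiotics. Doses, strains and whether the bacteria were alive are not given in the sources used here.

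The deposited table holds 1 count per gene and library, and its values were whole numbers. Per the submitters' processing notes, the genome build was Sscrofa11.1 and DESeq2 was used; the aligner, the counting tool, their versions and the annotation release are not given in the sources used here. The deposited count of each gene is taken to be the number of reads assigned to it, with no normalization applied, as the size of the column totals shows. Whether the counting used the strand of the read is not given either, so that reads of overlapping or antisense genes cannot be told apart. Reads shared by near-identical copies may have been split or dropped, so values of the interferon alpha genes, of the SLA genes of the major histocompatibility complex and of IL1B, which has a close copy in the pig genome, are uncertain in this respect.

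The table had 30686 rows keyed by NCBI gene ID. Of these, 30335 IDs matched the RefSeq gene table of Sscrofa11.1, from which symbols, chromosomes, starts and ends were taken; 351 rows had no symbol and held 0.515 to 1.04% of a library's counts, and they stayed in the totals and tests but are not named. More than 1 row carried the same symbol in 67 cases, and these rows were kept apart by ID. There were 0 columns of other series. All 18 libraries were used and none was left out.

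Counts were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16. Library sizes were scaled by TMM, genes were kept by filterByExpr over the 6 treatments with a minimum count of 10, which left 13592 genes, and 1 model with a mean per treatment and no block was fitted to all 18 libraries. P-values are two-sided and adjusted by Benjamini and Hochberg over the genes tested in a comparison, and a gene passed at an adjusted p of 0.05. Log2 fold changes carry the standard error (SE) implied by the F value of the test, and levels are CPM, counts scaled to the TMM-corrected library total, given as mean ± SD over the 3 libraries. The main comparisons were poly I:C, B. subtilis and E. faecium each against control, and both combined treatments against poly I:C alone. Secondary comparisons set the combined treatments against control and against the bacterium alone, and the bacteria against each other with and without poly I:C; a bacterium's change with poly I:C minus its change without it was tested as an interaction. Poly I:C against B. subtilis was added after the data had been seen.

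Gene lists were tested with camera of limma 3.58.1 with a preset correlation between genes of 0.01, two-sided, adjusted over the 36 lists with at least 3 tested members; the list of erythrocyte genes had 2. Each list was tested again with the correlation estimated from the residuals, and with fry, both in the fit without a block. Those residuals also hold the spread shared by the library sets described below. The 37 lists, fixed with the comparisons, tests and alternatives before the data were examined, were interferon-stimulated genes, type I and III interferons, proinflammatory cytokines, chemokines, anti-inflammatory and regulatory genes, NF-kB pathway and its feedback, pattern recognition receptors and adaptors, MHC class I and antigen processing, MHC class II and co-stimulation, inflammasome and pyroptosis, apoptosis, antimicrobial effectors, prostaglandin and leukotriene genes, complement, alveolar macrophage genes, M2-associated genes, cholesterol biosynthesis, cholesterol efflux and lipid handling, glycolysis, hypoxia response, nuclear-encoded oxidative phosphorylation, NRF2 oxidative stress response, metallothioneins and zinc transport, unfolded protein response, heat shock, immediate early genes, cell cycle, matrix remodelling and tissue factor, lysosome and phagocytosis, mitochondrially encoded genes and ribosomal proteins, and markers of T, NK and B cells, of neutrophils and mast cells, of epithelial cells, of endothelium and fibroblasts, of monocytes and dendritic cells, and of erythrocytes.

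Genes are named by a rule. In a main comparison it takes the 10 genes with the highest and the 10 with the lowest fold change among those past the threshold that moved the same way in all 3 differences between libraries of the same pig number, with a usual symbol and a mean of at least 1 log2 CPM. It adds up to 4 members of each list with the smallest p, whether or not they passed, and the genes followed in every comparison (IFNB1, MX1, ISG15, CXCL10, TNF, IL1B, IL6, IL10, CXCL8, TLR2, TLR3 and IFIH1). Secondary comparisons and interactions take 5 per direction and 2 per list. These numbers turned out not to pair the libraries, so that this part of the rule acts on arbitrary pairs in most comparisons. Genes outside the rule are said to have been chosen after their values were seen.

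The labels give the same pig numbers 1 to 3 in every treatment, so that libraries with 1 number should share an animal. This was checked with the correlation, across genes, of log2 CPM deviations from the treatment mean. Over the 45 pairs of libraries with the same number in different treatments the mean correlation was 0.0226, with a range of -0.527 to 0.739 and 17 pairs over 0.1. The libraries instead fell into 3 sets of 6, each with 1 library per treatment, within which the mean correlation was 0.616 (0.412 to 0.797), against -0.306 between sets. With the sets found on the odd chromosomes alone, the mean correlation within sets on the other chromosomes was 0.623. A fit with the pig number as a block was among the alternatives fixed beforehand; a fit with the 3 sets as a block was chosen after the data had been seen.

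Library totals ran from 16.3 to 27.3 megacounts (median 20.5). A gene with 0 counts in a library may lie at up to 0.0826 to 0.276 CPM there (3 counts of the scaled total), and such floors cover counting error only, since reads without molecular identifiers are not independent molecules. The lowest chi-square per degree of freedom was 69.5 over the 18 pairs of replicates of a treatment and 11 over all 153 pairs of libraries, where counting error alone would give 1, so that no library was a second copy of another. The test was tried on simulated data for poly I:C against control, with counts drawn around the control means at the fitted dispersions and library sizes and 200 genes changed. The changed genes were drawn only from those above a minimum expected count, so that the rates do not cover genes of low counts. There edgeR called 12% of 100 genes changed by 1 log2 unit and 74% of 100 changed by 2, with 4 false calls in 13039 genes tested; DESeq2 1.42.0 called 34% and 83%, with 32 false calls in 13035. Alternatives were RLE size factors, no filter on low counts, a filter of at least 50 counts in 3 libraries, DESeq2, the pig-number block in both tools, each comparison fitted on its own libraries, and leaving out each library or each pig number in turn.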

Results

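Gene expression was measured as read counts per gene in alveolar macrophages of healthy pigs after 24 hours with no addition, with poly I:C, with B. subtilis, with E. faecium, or with poly I:C and either bacterium, in 3 libraries per treatment (18 in all). The most abundant transcripts, chosen after their values were seen, were those of the iron-storing ferritin chain FTH1 with 3.84% of all counts on average, the neutrophil-attracting chemokine CXCL8 with 1.88%, the other ferritin chain FTL with 1.33% and the lipoprotein gene APOE with 0.787%. The mean total per library, in megacounts (M), was 23.8 ± 4 M in control (SD, n = 3 here and throughout), 19.8 ± 2.13 M with poly I:C, 19 ± 1.92 M with B. subtilis, 20.3 ± 5.26 M with E. faecium, 19.5 ± 3.88 M with B. subtilis and poly I:C, and 23.2 ± 0.593 M with E. faecium and poly I:C. The 10 most abundant genes took 9.61 to 17.1% of a library, and genes of the mitochondrial genome 0.485 to 1.34%. TMM factors, which correct for such differences in composition, ran from 0.664 in a library with B. subtilis and poly I:C to 1.38 in a library with E. faecium. Of the lists of markers of other cells, those of lymphocytes, neutrophils and mast cells, epithelium, and endothelium and fibroblasts passed in no main comparison, and that of monocytes and dendritic cells passed with B. subtilis against control.

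Treatment accounted for 51.3% of the variance of log2 CPM over the 13592 genes, the pig numbers of the labels for 9.59%, and the 3 library sets, found from the data, for 32.3%. Genes that marked a set, chosen after their values were seen, differed in every treatment. CLEC4E, a receptor for mycobacterial glycolipid (chromosome 5, 63219229 to 63228566), lay between 58.1 and 1120 CPM in set A, between 25.8 and 283 CPM in set B, and between 0.309 and 6.09 CPM in set C. The carboxylesterase CES1 lay between 60.8 and 110 CPM in set C and at 3.13 CPM or lower elsewhere, and the ion-pump regulator FXYD6 between 111 and 201 CPM in set C and at 9.58 CPM or lower elsewhere. With sets found on the odd chromosomes, 81 genes of the other chromosomes had a gap of more than 1 log2 unit between a set and all other libraries, against 0 genes with pig numbers and at most 34 in 100 random groupings.

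**Figure D1:**
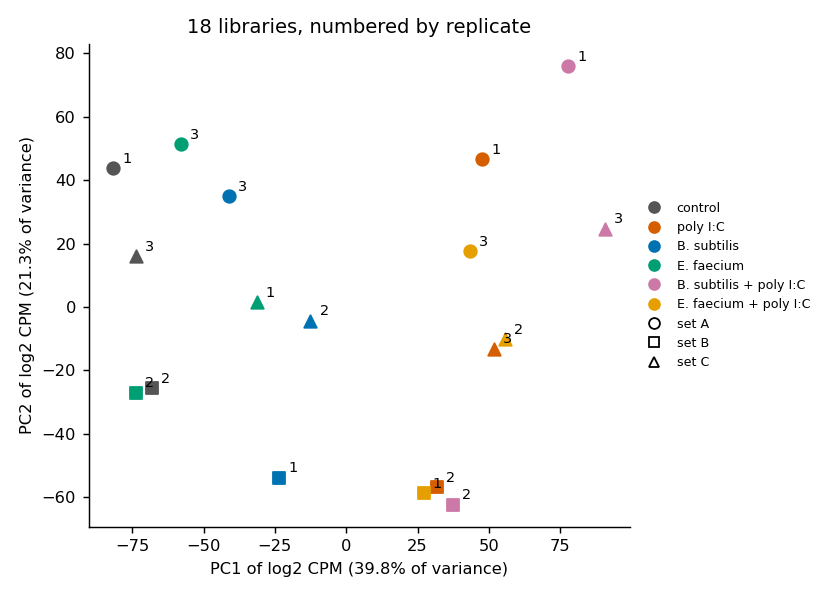
The 18 libraries on the first 2 principal components of log2 CPM (PC1 39.8% of the variance on the horizontal axis, PC2 21.3% on the vertical axis, both in component units), coloured by treatment, with the marker shape giving the library set and the digit the replicate number. The 3 control libraries lie between -81.61 and -68.14 on PC1.

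Poly I:C against control asks what double-stranded RNA alone does to these cells. Poly I:C raised the antiviral programme across the board: all 59 interferon-stimulated genes tested rose, with a median of 2.59 log2 units, and they included MX1, which blocks viral nucleoprotein, by 3.55 log2 units (SE 0.59, n = 3) and the ubiquitin-like ISG15 by 5.01 (SE 0.89). The interferon gene IFNB1 itself rose by 7.36 log2 units (SE 1.2), from 0.1 ± 0.148 to 15.7 ± 13.2 CPM. Inflammatory cytokines rose with it, among them TNF, an activator of NF-kB, by 6.06 log2 units (SE 1.05) and IL23A, the p19 chain of the T cell cytokine IL-23, by 7.53 (SE 1.09). TLR8, an endosomal sensor of single-stranded RNA, fell by 2.68 log2 units (SE 0.43). The resident alveolar macrophage genes did not pass as a list.

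The highest fold change among the genes given in full was that of CXCL11, a ligand of the T cell receptor CXCR3 (gene ID 100169744, chromosome 8, 71713790 to 71725669). It rose by 9.03 log2 units, from 0.773 ± 0.0353 to 407 ± 286 CPM (adjusted p = 2.83e-05). Its neighbour CXCL10 (494019, chromosome 8, 71693641 to 71695948) rose by 4.54 log2 units, from 288 ± 31.1 to 6710 ± 1770 CPM (adjusted p = 3.86e-05). MX1 (397128, chromosome 13, 204843049 to 204868927) went from 359 ± 323 to 4200 ± 473 CPM (adjusted p = 0.000592), and ISG15 (100145895, chromosome 6, 63363201 to 63364211) from 298 ± 304 to 9600 ± 5070 CPM (adjusted p = 0.000961). IFNB1 (445459, chromosome 1, 201850935 to 201851495) passed with an adjusted p of 0.000512. TNF (397086, chromosome 7, 23699635 to 23702393) went from 20.4 ± 2.54 to 1360 ± 377 CPM (adjusted p = 0.000771), and IL1B, the fever-inducing cytokine made as a precursor (397122, chromosome 3, 43670126 to 43677125), rose by 6.06 log2 units (adjusted p = 0.000818). IL6, which drives the acute phase, rose by 6.82 log2 units at a low level, from 0.0875 ± 0.126 to 9.54 ± 13.1 CPM (adjusted p = 0.0074). CXCL8 rose by 2.59 log2 units to 22300 ± 8270 CPM (adjusted p = 0.00102). The anti-inflammatory cytokine IL10, at 1.74 log2 units, did not pass (adjusted p = 0.0895), and neither did TLR3, the endosomal receptor of double-stranded RNA, at -0.03 (adjusted p = 0.981), whereas the cytosolic sensor IFIH1 rose by 3.06 log2 units.

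Among other genes past the threshold, the lymphocyte-attracting CCL20 rose by 7.41 log2 units, the granulocyte growth factor CSF3 by 7.01 and IL12A, a chain of IL-12, by 6.7. OASL, an antiviral relative of the oligoadenylate synthetases, also rose. The lowest changes were those of the phospholipase C-like PLCL1 at -3.58 log2 units, the homeobox factor VENTX at -3.43 and FAM105A, a relative of a linear-ubiquitin peptidase, at -3.43 (100518874, chromosome 16, 3964300 to 4000673; 16.9 ± 4.7 to 1.56 ± 0.377 CPM). The inhibitor of differentiation ID3 was at -2.84 and UBASH3B, a phosphatase that dampens receptor signals, at -2.83, both past the threshold. TLR8 (397384, X chromosome, 9551284 to 9616762) went from 64.2 ± 9.2 to 10 ± 2.09 CPM (adjusted p = 0.000419).

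Taken by list, the interferon-stimulated genes passed the camera test (adjusted p = 6.38e-47; adjusted p = 0.102 with an estimated correlation), with 59 of 59 past the threshold over all genes and 59 adjusted over the list alone; EPSTI1, a macrophage activator, rose by 2.76 log2 units and OASL by 6.64. Of 4 interferon genes tested 3 rose, and 4 adjusted over the list alone (camera adjusted p = 0.00528; adjusted p = 0.265 with an estimated correlation). Of 29 NF-kB pathway and feedback genes 23 rose, and 25 adjusted over the list alone, with the inhibitor NFKBIA at 2.66 and TNIP3, which restrains NF-kB, at 3.89 (adjusted p = 4.6e-17; adjusted p = 0.117 with an estimated correlation). Of 26 proinflammatory cytokines 14 rose, and 17 adjusted over the list alone, with EBI3, a chain of IL-27 and IL-35, at 4.48, its partner IL27 at 5.61 and the death ligand TNFSF10 at 3.61 (adjusted p = 1.13e-10; adjusted p = 0.185 with an estimated correlation). Of 24 chemokines 14 rose, and 14 rose and 1 fell adjusted over the list alone, with the T cell attractant CCL5 at 3.99 (adjusted p = 1.83e-08; adjusted p = 0.102 with an estimated correlation). Of 21 genes of MHC class I and antigen processing 12 rose and 1 fell (13 and 1 adjusted over the list alone; adjusted p = 2.74e-05; adjusted p = 0.153 with an estimated correlation), with the peptide transporter TAP1 at 1.73. Of 17 genes of MHC class II and co-stimulation 11 rose (13 adjusted over the list alone; adjusted p = 8.18e-06; adjusted p = 0.278 with an estimated correlation), with the T cell co-stimulators CD40 at 3.7 and CD80 at 2.92.

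Of 28 anti-inflammatory and regulatory genes 11 rose and 1 fell (12 and 1 adjusted over the list alone; adjusted p = 1.21e-05; adjusted p = 0.114 with an estimated correlation), with SOCS1, a brake on cytokine receptors, at 3.71 and the immune-regulatory lectin LGALS9 at 2.22. Of 20 apoptosis genes 12 rose (13 up and 1 down adjusted over the list alone; adjusted p = 6.29e-05; adjusted p = 0.114 with an estimated correlation), with the death-promoting PMAIP1 at 3.42 and the death-preventing BCL2 at 3.78. Of 24 genes of the unfolded protein response 12 rose (13 adjusted over the list alone; adjusted p = 3.1e-05; adjusted p = 0.265 with an estimated correlation), with its transcription factor XBP1 at 2.02. Of 19 complement genes 9 rose and 3 fell (9 and 4 adjusted over the list alone; adjusted p = 0.026; adjusted p = 0.29 with an estimated correlation), with the protease C1R at 3.49 and the cell-surface inhibitor CD46 at -1.32. Of 23 genes of matrix remodelling and tissue factor 7 rose (9 adjusted over the list alone; adjusted p = 0.0132; adjusted p = 0.278 with an estimated correlation), with the protease inhibitor TIMP1 at 3.91. Of 20 antimicrobial effectors 5 rose (5 adjusted over the list alone; adjusted p = 0.0402; adjusted p = 0.29 with an estimated correlation), with ACOD1, which makes itaconate, at 4.67 and the tryptophan-degrading IDO1 at 4.4.

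The other lists did not pass, although members did. Of 30 pattern recognition receptors and adaptors 10 rose and 3 fell around a median of 0.00, with the DNA sensor MB21D1 at 2.9. Of 14 genes of inflammasome and pyroptosis 7 rose and 2 fell, with the cytokine-cleaving CASP1 at 2.48 (camera adjusted p = 0.0535). Of 34 alveolar macrophage genes 5 rose and 3 fell, with a median of -0.07, and SIGLEC1, a sialic acid receptor that captures virus, was at 2.36 and the TGF-beta receptor chain TGFBR2 at -1.68. Lipid metabolism was mixed: 2 of 23 cholesterol biosynthesis genes fell, and 2 genes of cholesterol efflux and lipid handling rose and 2 fell, with the exporter ABCA1 at 2.68. Of the 37 cell cycle genes 1 rose and 5 fell, with the replication regulator E2F1 at -1.77 and a median of -0.3. Of 19 hypoxia response genes 2 rose and 5 fell, with the carbonic anhydrase CA12 at -3.35, and of 25 glycolysis genes 2 rose and 1 fell. Prostaglandin and leukotriene genes gave 3 up and 1 down, NRF2 genes 3 up with the haem-degrading HMOX1 at 2.3, M2-associated genes 1 up, immediate early genes 5 up with the transcription factor ATF3 at 1.77, and heat shock genes 2 up and 1 down. Lysosome and phagocytosis genes gave 5 up and 2 down, metallothioneins and zinc transport 1 up and 1 down, and nuclear-encoded oxidative phosphorylation 2 down. None of 72 ribosomal proteins (median 0.3) and none of 12 mitochondrially encoded genes passed. Among marker lists, monocytes and dendritic cells had 4 up with the LPS co-receptor CD14 at 1.83, T, NK and B cells 1 up, endothelium and fibroblasts 2 up, epithelial cells, neutrophils and mast cells 0, and both erythrocyte genes tested did not pass.

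In total 3055 genes passed for poly I:C against control with edgeR, 1757 up and 1298 down. Without the libraries numbered 1 the total was 1452, and without those numbered 3 it was 636. The numbers follow the sets in control and poly I:C, so that each of these fits left out the same set from both. From B. subtilis, E. faecium, and E. faecium with poly I:C, each fit left out libraries of other sets. Those treatments share the estimate of the spread, so that the totals do not show what a single set contributes. With an estimated correlation 0 of the 13 list calls held in this comparison, 7 of 13 held for B. subtilis against control, 7 of 16 for E. faecium against control and 1 of 15 for the E. faecium interaction, and in every other comparison 0 held. The correlation was estimated in the fit without a block, where the residuals hold the library sets. It was not estimated with the sets as a block, so that how far the lost calls depend on the sets was not tested.

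**Figure D2:**
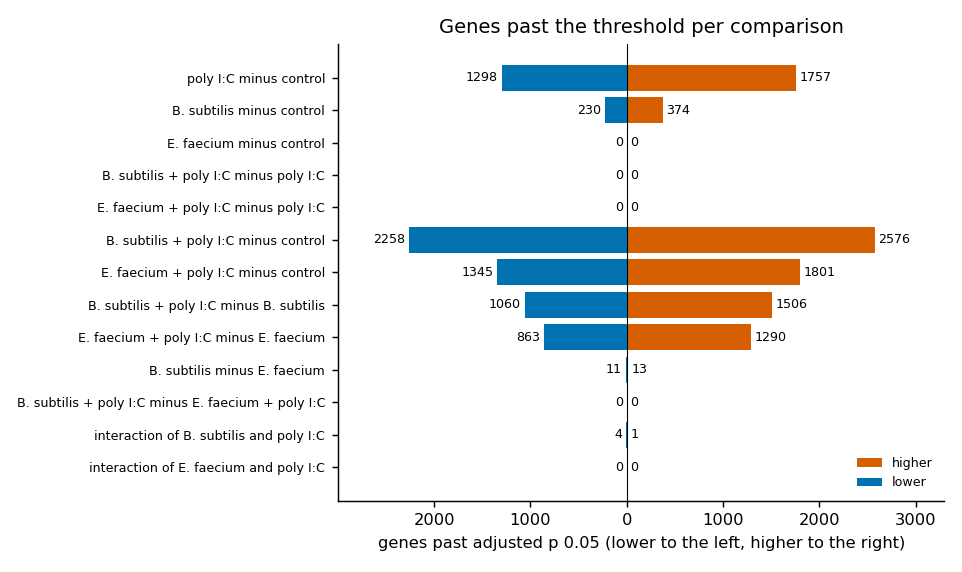
Bars give the number of genes past an adjusted p of 0.05 in each comparison, higher and lower in the first treatment named. Bars for poly I:C against control reach 1757 higher and 1298 lower, and those for E. faecium against control and for both combined treatments against poly I:C are at 0.

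B. subtilis against control asks what this bacterium alone does. It raised cytokines that NF-kB drives: IL23A rose by 9.03 log2 units (SE 1.16, n = 3), IL1B by 6.85 (SE 1.1), TNF by 5.92 (SE 1.04) and the neutrophil chemokine CXCL2 by 5.47 (SE 0.85). Of 59 interferon-stimulated genes 1 passed upward in this fit without a block, and IFNB1, MX1, ISG15 and CXCL10 did not pass. MX1, ISG15 and CXCL10 nonetheless lay above the control library of the same set in every set, and the list lay higher than control at a median of 0.81 log2 units. That list call did not hold with an estimated correlation. Both endosomal sensors of single-stranded RNA fell, TLR8 with a change of -3.18 log2 units (SE 0.44) and TLR7 of -2.11 (SE 0.35), and so did CSF1R, the receptor of the macrophage growth factors, with -1.29 (SE 0.27).

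IL23A (100155546, chromosome 5, 21732416 to 21733981) went from 1.79 ± 0.949 to 938 ± 198 CPM (adjusted p = 0.000767), and CCL20 (553951, chromosome 15, 129172743 to 129176069) rose by 8 log2 units to 527 ± 180 CPM (adjusted p = 0.001). IL1B went from 97.5 ± 112 to 11200 ± 3790 CPM (adjusted p = 0.00287), TNF to 1240 ± 544 CPM (adjusted p = 0.00495), and CXCL8 (396880, chromosome 8, 69932646 to 69935861) from 3690 ± 1420 to 32400 ± 2900 CPM (adjusted p = 0.00208). IL6 rose by 6.13 log2 units to 5.89 ± 7.2 CPM (adjusted p = 0.0432). TLR2, the receptor of bacterial lipopeptides, rose by 0.97 (adjusted p = 0.0426). IFNB1 was at 0.437 ± 0.335 CPM against 0.1 ± 0.148 (adjusted p = 0.423), and MX1 at 745 ± 386 CPM against 359 ± 323 (adjusted p = 0.348), being above the control library of its set in each set (316 against 125, 1060 against 727 and 858 against 225 CPM). ISG15 was also higher in sets A, B and C (255 against 60.8, 981 against 640 and 829 against 192 CPM). So was CXCL10 (308 against 276, 480 against 264 and 589 against 323 CPM). TLR8 went from 64.2 ± 9.2 to 7.07 ± 3.54 CPM (adjusted p = 0.001), TLR7 (100037296, X chromosome, 9573178 to 9576987) from 37.8 ± 4.87 to 8.73 ± 2.92 (adjusted p = 0.00351), and CSF1R from 393 ± 84.9 to 160 ± 34 (adjusted p = 0.0129). Other genes that fell were FAM105A by 2.57, the anion transporter SLCO2B1 by 2.5, the mRNA-decay factor ZFP36L2 by 2.38 and the complement receptor C5AR1 by 1.94.

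Of 29 NF-kB pathway genes 16 rose, and 23 adjusted over the list alone, with TNIP3 at 3.04 and the NF-kB-induced IER3 at 4.04 (camera adjusted p = 2.42e-28). Of 26 proinflammatory cytokines 12 rose, and 17 adjusted over the list alone, with IL1A at 4.45 (adjusted p = 5.57e-24). Of 24 chemokines 7 rose, and 9 adjusted over the list alone (adjusted p = 3.28e-11). Anti-inflammatory and regulatory genes gave 8 up and 1 down, 12 and 1 adjusted over the list alone, with SOCS3, which limits IL-6 signals, at 3.38 (adjusted p = 3.7e-09), matrix remodelling 4 up with TIMP1 at 4.35, apoptosis 4 up with the death receptor FAS at 1.47, and monocyte and dendritic cell markers 3 up with the dendritic cell factor BATF3 at 4.08. These 7 lists held with an estimated correlation. Interferon-stimulated genes, at a median of 0.81, were up as a list (adjusted p = 2.28e-10), with STAT2, which carries the interferon signal, as the only member past the threshold; adjusted p = 0.337 with an estimated correlation. Also past with the preset correlation only were immediate early genes (median 1.12; adjusted p = 0.122 with an estimated correlation), the unfolded protein response (0.5; adjusted p = 0.202 with an estimated correlation), antimicrobial effectors (0.97; adjusted p = 0.138 with an estimated correlation), inflammasome genes (0.28; adjusted p = 0.158 with an estimated correlation) and, downward, the cell cycle (-0.5; adjusted p = 0.158 with an estimated correlation). Interferons, alveolar macrophage genes, ribosomal proteins and the remaining lists did not pass.

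In total 604 genes passed for B. subtilis against control with edgeR, 374 up and 230 down, and 1151 with DESeq2. Without the libraries numbered 3 no gene passed, and without those numbered 1 the total was 56; the libraries of 1 number belong to different sets in these treatments, and with the sets as a block, chosen after seeing the data, 2504 genes passed.

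E. faecium against control asks the same of the second bacterium. No single gene passed in this comparison. Cytokines that B. subtilis raised were higher here too, without passing: TNF was 5.27 log2 units higher (SE 1.01, n = 3), IL23A 5.22 (SE 0.99), CCL20 4.2 (SE 0.92) and the monocyte chemokine CCL4 3.37 (SE 0.71). As lists, NF-kB pathway genes, cytokines and chemokines passed upward. The libraries differed, with TNF at 1970, 26 and 356 CPM in replicates 1 to 3 against 20.4 ± 2.54 in control.

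In edgeR TNF had an adjusted p of 0.481, as had IL23A, and CCL20 and CCL4 had 0.69. IL1B was at 990 ± 1120 CPM against 97.5 ± 112 (adjusted p = 1), IFNB1 at 1.49 ± 1.87 against 0.1 ± 0.148 (adjusted p = 1), and MX1 at 549 ± 241 against 359 ± 323. All 29 NF-kB pathway genes were above control at a median of 0.87, and 16 passed adjusted over the list alone (camera adjusted p = 3.47e-46), with IER3 at 2.15 and NFKBIA at 1.38. Proinflammatory cytokines, at a median of 1.76, had 10 adjusted over the list alone (adjusted p = 4.87e-32), chemokines 5, immediate early genes 4 with the stress-induced JUNB at 1.32, inflammasome genes 3 with the pyrin gene MEFV at 3, anti-inflammatory genes 2 and matrix remodelling 0; these 7 lists held with an estimated correlation. The other 9 lists passed with the preset correlation only: interferon-stimulated genes (median 0.49, 58 of 59 above control; adjusted p = 0.175 with an estimated correlation), interferons (1.96; adjusted p = 0.197 with an estimated correlation), MHC class I (0.17; adjusted p = 0.238 with an estimated correlation), MHC class II (0.24; adjusted p = 0.394 with an estimated correlation), antimicrobial effectors (0.3; adjusted p = 0.104 with an estimated correlation), apoptosis (0.17; adjusted p = 0.119 with an estimated correlation), the unfolded protein response (0.08; adjusted p = 0.387 with an estimated correlation), NRF2 genes (0.13; adjusted p = 0.23 with an estimated correlation) and pattern recognition receptors (0.11; adjusted p = 0.0531 with an estimated correlation).

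With edgeR 0 genes passed, and 278 had an unadjusted p under 0.05; the smallest adjusted p was 0.481. DESeq2 called 38 genes, all higher with E. faecium, and edgeR called 36, all higher, without E. faecium replicate 2. With fry 0 lists passed.

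**Figure D3:**
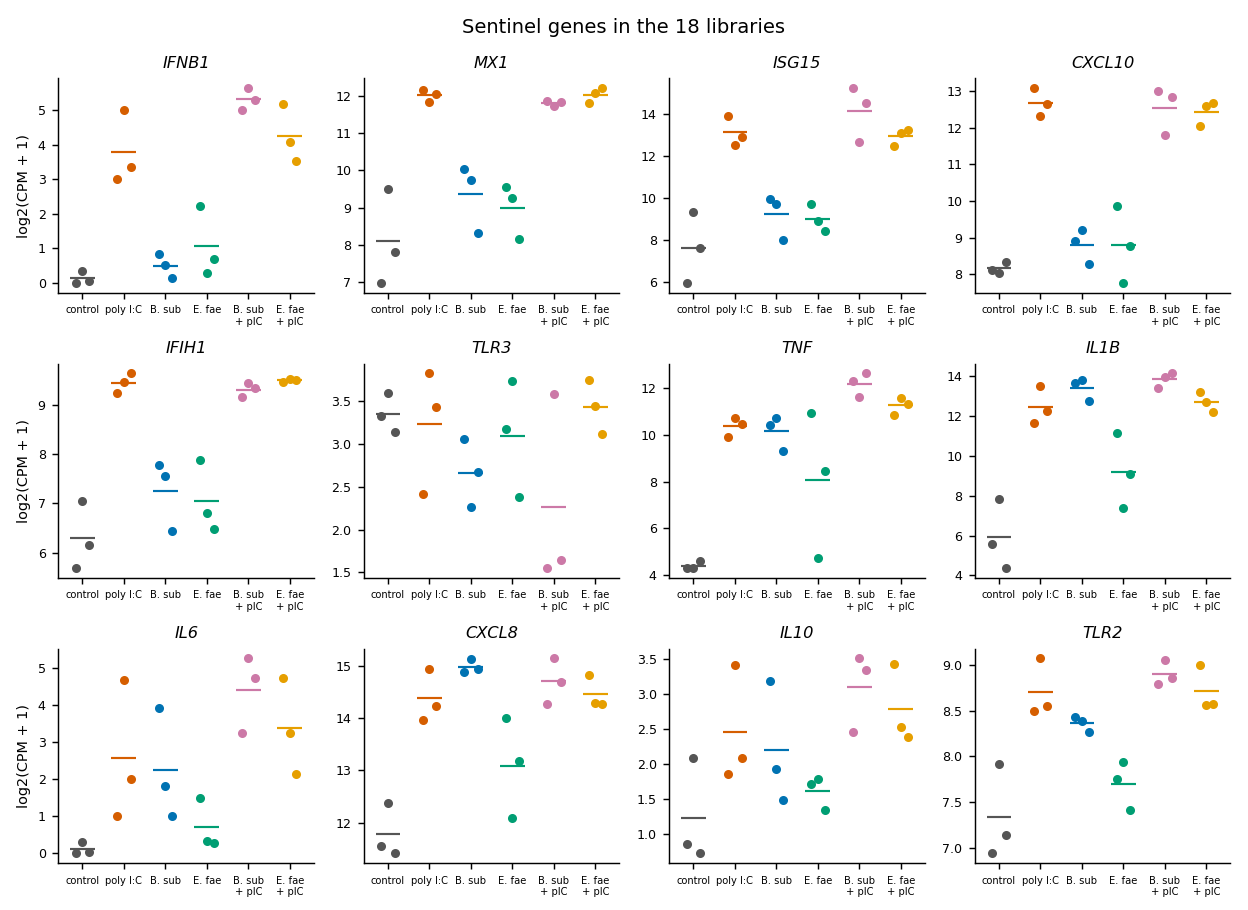
Expression of the genes followed in every comparison, as log2 of CPM + 1 on the vertical axis, in each of the 18 libraries, with the 6 treatments along the horizontal axis and 1 point per library. TNF in the 3 libraries with E. faecium lies at 1970, 26 and 356 CPM.

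B. subtilis with poly I:C against poly I:C alone asks whether the bacterium changes the response to double-stranded RNA. The interferon-stimulated genes did not pass as a list: their median was -0.13, with MX1 at -0.21 log2 units (SE 0.56, n = 3) and CXCL10 at -0.08 (SE 0.45), whereas ISG15 was at 1.24 (SE 0.76) and did not pass either. Cytokines lay higher as a list (adjusted p = 0.436 with an estimated correlation), with TNF at 1.85 (SE 0.87) and EBI3 at 1.9 (SE 0.5), but no single gene passed. All 72 ribosomal proteins were above poly I:C alone, at a median of 0.86, but replicate 2 did not share in this, with 2.05% of its counts on them against 2.16% in the poly I:C library of its set, where replicates 1 and 3 had 4.43 against 3.03% and 3.34 against 1.63%. The genes with the smallest p included 2 of protein folding in the endoplasmic reticulum, SDF2L1 at 1.3 (SE 0.29) and MANF at 1.06 (SE 0.26).

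TNF was at 4890 ± 1630 CPM against 1360 ± 377 (adjusted p = 0.477), EBI3 at 313 ± 186 against 83.6 ± 17 (adjusted p = 0.447), IFNB1 at 39.2 ± 8.69 against 15.7 ± 13.2 (adjusted p = 0.591), and IL1B was 1.19 log2 units higher (adjusted p = 0.643). SDF2L1 was at 45.3 ± 17.8 CPM against 18.3 ± 5.31 and MANF at 141 ± 23.7 against 67.7 ± 19.2 (adjusted p = 0.447 for both). On the lower side were TLR7 at -1.32, 15.3 ± 6.72 CPM against 38.4 ± 6.44, and MYD88, the adaptor of most Toll-like receptors, at -1.29. Of the ribosomal proteins 61 passed adjusted over the list alone (camera adjusted p = 2.85e-37; adjusted p = 0.436 with an estimated correlation), with RPS29 at 1.16 and RPLP2 at 1.26. Oxidative phosphorylation genes were at 0.51 with 30 of 31 above poly I:C alone (adjusted p = 2.25e-10), proinflammatory cytokines at 1.18 (adjusted p = 6.04e-07), NF-kB genes at 0.4, with the inhibitor TNIP2 at 1.22 (adjusted p = 4.25e-06), the unfolded protein response at 0.37 (adjusted p = 1.48e-05), chemokines at 0.49, interferons at 1.68 and antimicrobial effectors at 0.57. None of these 8 lists held with an estimated correlation (adjusted p = 0.436 to 0.474 with an estimated correlation).

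With edgeR 0 genes passed and 1423 had an unadjusted p under 0.05; DESeq2 called 28. Without replicate 2 of the combined treatment edgeR called 2087 genes, 914 up and 1173 down. With the library sets as a block, edgeR stayed at 0 and DESeq2 called 949, and TNF was higher with B. subtilis in each set (5130 against 959, 3160 against 1710 and 6390 against 1420 CPM).

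E. faecium with poly I:C against poly I:C alone asks the same of the second bacterium. Here the antiviral genes did not pass either, with MX1 at 0.01 log2 units (SE 0.54, n = 3), CXCL10 at -0.26 (SE 0.45), IFNB1 at 0.39 (SE 0.82) and a list median of 0 for interferon-stimulated genes. TNF was at 0.88 (SE 0.85) and IL1B at 0.07 (SE 0.85), and neither passed. Immediate early genes lay higher as a list (adjusted p = 0.514 with an estimated correlation), with EGR1, an early growth response factor, at 1.28 (SE 0.69).

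Every gene had an adjusted p of 1. TNF was at 2510 ± 619 CPM against 1360 ± 377, EGR1 at 76.7 ± 46.5 against 31.6 ± 13.9, and IL12B, the chain shared by IL-12 and IL-23, at 24.6 ± 30.8 against 1.86 ± 2.55. The B cell attractant CXCL13 was at -1.63 and the decoy receptor IL1R2 at -1.42. Upward lists were immediate early genes (median 0.35; camera adjusted p = 1.93e-08), NF-kB genes (0.18; adjusted p = 0.884 with an estimated correlation), anti-inflammatory genes (0.23; adjusted p = 0.793 with an estimated correlation), cytokines (0.19; adjusted p = 0.884 with an estimated correlation) and matrix remodelling (0.14; adjusted p = 0.793 with an estimated correlation). Downward were ribosomal proteins, at -0.28 with 0 of 72 above poly I:C alone (camera adjusted p = 1.81e-13; adjusted p = 0.884 with an estimated correlation), and oxidative phosphorylation, at -0.19 (adjusted p = 0.884 with an estimated correlation). With edgeR 0 genes passed and 38 had an unadjusted p under 0.05; DESeq2 called 0.

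**Figure D4:**
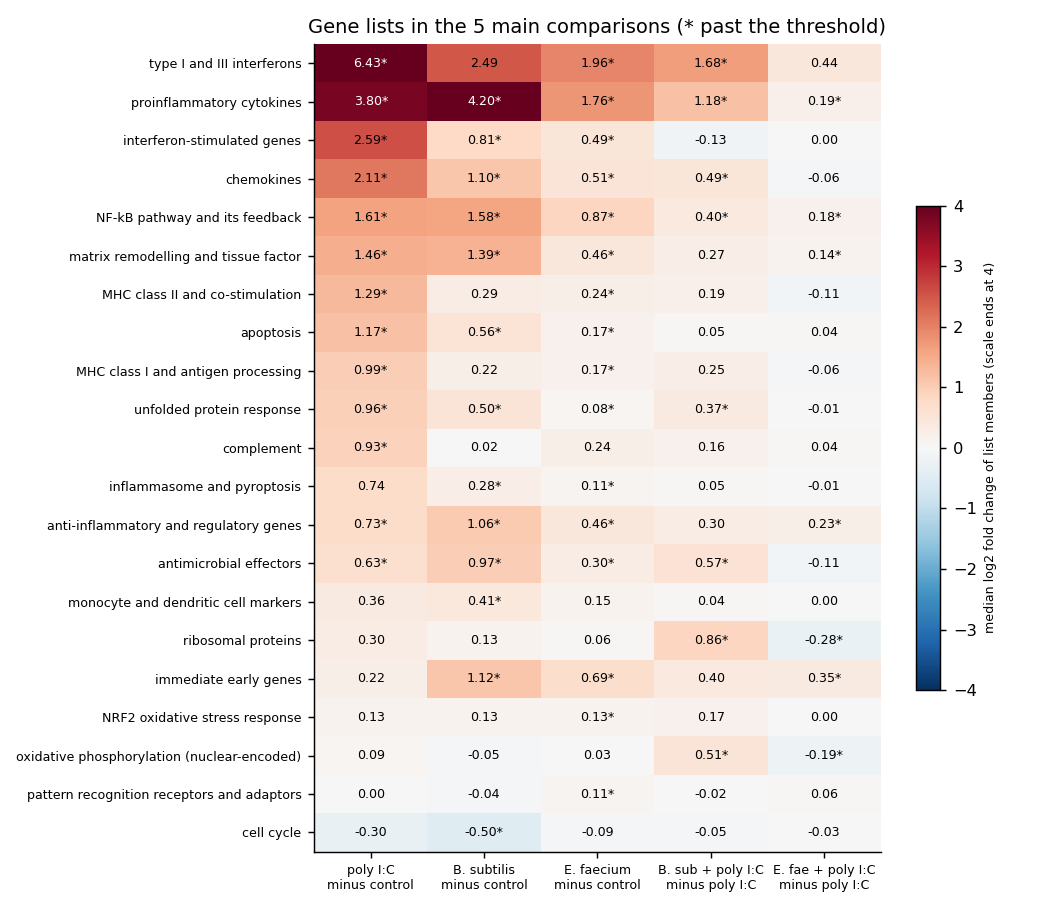
Median log2 fold change of each gene list (vertical axis) in the 5 main comparisons (horizontal axis), on a colour scale that ends at 4 log2 units either way; an asterisk marks an adjusted p under 0.05 with the preset correlation. The interferon-stimulated genes are at 2.59 with poly I:C, 0.81 with B. subtilis and 0.49 with E. faecium against control.

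Both combined treatments were also set against control, which asks whether the poly I:C response stands in the presence of a bacterium. It did: MX1 rose by 3.34 log2 units with B. subtilis and poly I:C and by 3.56 with E. faecium and poly I:C, CXCL10 by 4.47 and 4.29, and ISG15 by 6.25 and 4.75. IFNB1 rose by 8.68 (SE 1.24, n = 3) and 7.74 (SE 1.21), TNF by 7.91 (SE 1.14) and 6.95 (SE 1.09), IL1B by 7.25 and 6.14, and IL6 by 8.15 and 7.22. IL10 rose by 2.37 with B. subtilis and poly I:C, and was at 2.01 with E. faecium and poly I:C without passing.

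With B. subtilis and poly I:C 58 of 59 interferon-stimulated genes rose (median 2.57), 27 of 29 NF-kB genes (2.01), 20 of 26 cytokines with EBI3 at 6.39, 4 of 4 interferons (8.07), 17 of 24 unfolded protein response genes and 61 of 72 ribosomal proteins (1.15). Against the control library of the same set the ribosomal median was 1.59 and 1.39 in replicates 1 and 3, which had the lowest TMM factors, and 0.12 in replicate 2. PIK3IP1, a negative regulator of PI3 kinase, fell by 3.96 and TLR8 by 3.7. With E. faecium and poly I:C 59 of 59 interferon-stimulated genes rose (2.55; adjusted p = 0.0765 with an estimated correlation), 23 of 29 NF-kB genes (1.72), 19 of 26 cytokines (4.14) and 10 of 17 MHC class II genes, and FAM105A fell by 3.69 and ID3 by 3.48. The totals with edgeR were 4834 genes (2576 up, 2258 down) with B. subtilis and poly I:C and 3146 (1801 up, 1345 down) with E. faecium and poly I:C; without the libraries numbered 3 they were 1342 and 877. In lists, 15 and 14 passed upward; with an estimated correlation the smallest adjusted p was 0.123 and 0.0765.

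Each combined treatment against its bacterium alone asks what poly I:C adds to a cell that has met the bacterium. It added the antiviral genes, while most of the 26 cytokines did not pass. Against B. subtilis, CXCL11 rose by 8.26 log2 units (SE 0.95, n = 3), IFNB1 by 6.45 (SE 1.09), ISG15 by 5.04 (SE 0.89), CXCL10 by 3.79 (SE 0.5) and MX1 by 2.28 (SE 0.56), whereas TNF at 1.98, IL1B at 0.41 and CXCL8 at -0.24 did not pass. Against E. faecium, CXCL11 rose by 8.11 (SE 0.95), IFNB1 by 3.82 (SE 0.94), ISG15 by 3.86, CXCL10 by 3.4 and MX1 by 2.95, and IL1B also rose, by 2.79 (SE 0.91).

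Against B. subtilis 44 of 59 interferon-stimulated genes rose, and 53 adjusted over the list alone (median 1.78; adjusted p = 0.305 with an estimated correlation). MHC class I gave 13 of 21 up with TAP1 at 1.4, MHC class II 10 of 17 with the class II chain SLA-DRA at 1.66, interferons 4 of 4, NF-kB genes 10 of 29 and ribosomal proteins 40 of 72, which replicate 2 did not share, with 2.05% of its counts on them against 2.28% in the B. subtilis library of its set. IL4I1, which degrades aromatic amino acids, rose by 4.72, and VENTX fell by 3.26. Against E. faecium 53 of 59 interferon-stimulated genes rose, and 59 adjusted over the list alone (median 2.16; adjusted p = 0.199 with an estimated correlation), and 12 of 29 NF-kB genes, 10 of 26 cytokines and 7 of 24 chemokines did. The muscarinic receptor CHRM3 rose by 6.19 (SE 0.57), from 0.336 ± 0.046 to 25.3 ± 10.2 CPM, and TNF at 1.68 and IL6 at 4.07 did not pass. The totals with edgeR were 2566 genes (1506 up, 1060 down) against B. subtilis and 2153 (1290 up, 863 down) against E. faecium; without the libraries numbered 3 they were 2 and 146. In lists, 12 and 11 passed upward, and 0 of either held with an estimated correlation.

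B. subtilis against E. faecium asks where the bacteria differ. EBI3 was higher with B. subtilis by 3.52 log2 units (SE 0.54, n = 3), BATF3 by 2.75 (SE 0.51) and MCEMP1, a mast cell membrane protein gene also induced in monocytes, by 2.36 (SE 0.34). TLR8 was lower with B. subtilis by 2.77 (SE 0.43) and TLR7 by 1.91 (SE 0.35). IL1B, CXCL8, CCL20 and TNF did not differ past the threshold in this fit without a block. Within sets A, B and C, IL1B was nonetheless higher with B. subtilis (6910 against 537, 12700 against 166 and 14100 against 2270 CPM). So was CXCL8 (31500 against 9320, 30200 against 4330 and 35700 against 16400 CPM), whereas TNF was lower in set C (1700 against 1970 CPM).

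EBI3 (100522599, chromosome 2, 74530728 to 74540433) was at 67.1 ± 33.5 CPM with B. subtilis and 5.84 ± 2.52 with E. faecium (adjusted p = 0.014), BATF3 at 78.5 ± 15.9 and 11.7 ± 6.65 (adjusted p = 0.0413), MCEMP1 at 210 ± 38.3 and 40.8 ± 11.2 (adjusted p = 0.014), and TLR8 at 7.07 ± 3.54 and 48 ± 30.5 (adjusted p = 0.014). IL1B was 3.5 log2 units higher with B. subtilis (adjusted p = 0.159), CXCL8 1.69 (adjusted p = 0.158) and TNF 0.66 (adjusted p = 0.995). Cytokines (median 1.67; 12 adjusted over the list alone; adjusted p = 0.099 with an estimated correlation), NF-kB genes (0.54; adjusted p = 0.16 with an estimated correlation) and 11 further lists were higher, and alveolar macrophage genes (-0.19; adjusted p = 0.315 with an estimated correlation), cell cycle (-0.34) and lysosome genes (-0.21) lower; 0 of the 16 held with an estimated correlation. In total 24 genes passed with edgeR, 13 higher and 11 lower with B. subtilis, and 276 with DESeq2. Leaving out any pig number took the edgeR total to 0, but leaving out number 1 or 2 takes libraries of different sets from these treatments; with the sets as a block it was 927.

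The same contrast in the presence of poly I:C had no gene past the threshold. EBI3 was 1.96 log2 units higher with B. subtilis and poly I:C (SE 0.5, n = 3), BATF3 2.01, the secreted chaperone CRELD2 1.14 and SDF2L1 1.38 (SE 0.29), and MYD88 1.52 lower. All 72 ribosomal proteins were higher at a median of 1.14 (72 adjusted over the list alone; camera adjusted p = 3.7e-44; adjusted p = 0.624 with an estimated correlation), with RPS29 at 245 ± 147 CPM against 88.9 ± 5.03. The counts assigned to ribosomal proteins were 4.43, 2.05 and 3.34% of the libraries with B. subtilis and poly I:C and 1.91 ± 0.155% with E. faecium and poly I:C, so that replicate 2 did not stand apart. Oxidative phosphorylation genes were at 0.75 with 17 adjusted over the list alone, and 7 lists were higher, of which 0 held with an estimated correlation. With edgeR 0 genes passed, 2245 had an unadjusted p under 0.05 and the smallest adjusted p was 0.167; DESeq2 called 595, and edgeR 3316 without replicate 2 of B. subtilis and poly I:C. With the library sets as a block, chosen after seeing the data, edgeR called 1157 genes and DESeq2 2680, and on the chromosomes not used to find the sets edgeR went from 0 to 770. Deviations of whole libraries recur on all chromosomes, so that this rise is no independent check.

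The interaction of B. subtilis and poly I:C asks whether the bacterium's effect differs once poly I:C is present. It was smaller for VDR, the vitamin D receptor, and for SH2D1B, an adaptor of SLAM receptors. VDR was at 16.8 ± 3.4 CPM in control, 48.7 ± 14.3 with poly I:C, 128 ± 29.6 with B. subtilis and 59 ± 11.2 with both, so that B. subtilis added 2.93 log2 units without poly I:C and 0.28 with it (difference -2.65, SE 0.42, n = 3). SH2D1B went from 2.52 to -0.4 (difference -2.92, SE 0.4), and the interferon-inducing kinase IKBKE from 1.57 to 0.11 (difference -1.46, SE 0.24). FAM105A, lowered by each stimulus, had a difference of 2.59 (SE 0.41).

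VDR (396628, chromosome 5, 78205807 to 78266505) had an adjusted p of 0.0456, SH2D1B (100620669, chromosome 4, 88097534 to 88129792) of 0.033, IKBKE of 0.0466 and FAM105A of 0.0456. The last was LOC100626929, uncharacterized and chosen after its values were seen, with a difference of -3.51 (adjusted p = 0.0456). Cytokines had differences further below 0 but did not pass, with IL23A at -7.14 (SE 1.28, adjusted p = 0.0727), CCL20 at -6.16 (adjusted p = 0.0968), IL1B at -5.66 (adjusted p = 0.174) and TNF at -4.08 (adjusted p = 0.343). Such a value means a smaller fold change and does not by itself mean a lower level. TNF lay between 637 and 1700 CPM with B. subtilis alone and between 3160 and 6390 CPM with both stimuli. Of 13 lists past the threshold 10 were negative, among them cytokines (median -3.51, 13 adjusted over the list alone; adjusted p = 0.128 with an estimated correlation), NF-kB genes (-1.18, 11 adjusted over the list alone; adjusted p = 0.165 with an estimated correlation) and interferon-stimulated genes (-0.88; adjusted p = 0.416 with an estimated correlation), and ribosomal proteins, oxidative phosphorylation and the cell cycle were positive. In total 5 genes passed with edgeR, 0 with the pig number as a block, 1 with RLE size factors and 115 with DESeq2. Leaving out any pig number took the total to 0, and with the sets as a block it was 521.

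For E. faecium the interaction had no gene past the threshold. IL23A had a difference of -4.73 log2 units (SE 1.22, n = 3), TNF of -4.38 (SE 1.24), CCL20 of -3.96 and IFNB1 of -3.54, each with an adjusted p of 1. All 15 lists past the threshold were negative, which by itself does not mean lower levels with both stimuli. TNF was at 785 ± 1040 CPM with E. faecium alone and at 2510 ± 619 CPM with both. Chemokines (median -0.76; adjusted p = 0.0309 with an estimated correlation) held, but not with fry, where the adjusted p was 0.77; cytokines (-1.87; adjusted p = 0.131 with an estimated correlation), NF-kB genes (-0.64; adjusted p = 0.131 with an estimated correlation) and interferon-stimulated genes (-0.47; adjusted p = 0.379 with an estimated correlation) did not. With edgeR 0 genes passed and 95 had an unadjusted p under 0.05; DESeq2 called 0.

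The responses to the bacteria resembled each other across genes, which are not independent replicates, and 6 pairs of responses were compared. The log2 fold changes of B. subtilis and E. faecium against control had a Pearson r of 0.703 (Spearman rho 0.657). Simulated treatments without effect that share a control gave 0.445 to 0.528, and the covariance was 0.26 against at most 0.149. All simulations drew genes and libraries independently, without the library sets. Their ranges thus leave out deviations that genes share within a library, and are no measure of chance. For B. subtilis and poly I:C against control r was 0.685 (rho 0.656; covariance 0.679), with 267 genes higher in both, 167 lower in both and 1 opposite, where independent calls would give 48.3 and 22, values that ignore the control they share. For E. faecium and poly I:C r was 0.57 (rho 0.549, covariance 0.299). Without the libraries numbered 1, r was 0.399 for both bacteria, 0.535 for B. subtilis and poly I:C, and 0.159 for E. faecium and poly I:C. Both bacteria on top of poly I:C had r = 0.111 (rho -0.118), under the 0.443 to 0.529 of simulated treatments that share a reference. The effect of B. subtilis without and with poly I:C had r = 0.277 (rho 0.246), and that of E. faecium 0.151 (rho 0.0973). Genes with a mean of at least 3 log2 CPM gave -0.412 for both bacteria on top of poly I:C.

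A contrast added after the data were seen, poly I:C against B. subtilis, asks where levels differ between these stimuli. It cannot tell genes raised by poly I:C alone from genes raised by both to different degrees. The antiviral programme was higher with poly I:C: 48 of 59 interferon-stimulated genes passed upward, and 58 adjusted over the list alone, with a median of 1.88 (camera adjusted p = 2.9e-46; adjusted p = 0.218 with an estimated correlation). Genes of MHC class I (4 up, median 0.67) and MHC class II (5 up, 1.15) were higher as lists, and hypoxia (-0.61), cholesterol biosynthesis (-0.56) and immediate early genes (-0.64) lower; with an estimated correlation 0 of the 9 list calls held. In total 1218 genes passed with edgeR, 820 higher and 398 lower with poly I:C. Without the libraries numbered 3 the total was 1.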

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

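The tests of the interactions and of other splits of the libraries were planned, and the gene LOC100626929 was chosen after its values were seen. In 5 genes the effect of B. subtilis differed with and without poly I:C past the threshold of edgeR. VDR had a difference of -2.65 log2 units, SH2D1B of -2.92, IKBKE of -1.46 and the uncharacterized LOC100626929 of -3.51, each raised by B. subtilis alone and little changed by it once poly I:C was present, and FAM105A had 2.59, being lowered by B. subtilis alone and already low with poly I:C. These 4 were also raised by poly I:C on its own. VDR was lower with both stimuli (59 ± 11.2 CPM) than with B. subtilis alone (128 ± 29.6 CPM), and so was SH2D1B (18.4 ± 2.73 against 64.8 ± 18.2 CPM), which a ceiling on expression would not give; IKBKE, at 119 ± 7.29 against 131 ± 4.63 CPM, may have met one. The number of genes went from 5 with edgeR to 115 with DESeq2 and to 0 with the pig number as a block, although the numbers do not pair the libraries. With the library sets as a block, chosen after seeing the data, it was 521 with edgeR and 1183 with DESeq2, and on the chromosomes not used to find the sets it went from 3 to 277. Deviations of whole libraries recur on all chromosomes, so that this rise is no independent check. The splits ignore the sets and shuffle the libraries over all treatments of the interaction. A split can thus carry the effect of poly I:C or of B. subtilis into the contrast, and is no measure of chance for an interaction. In 8 of 100 splits, the real one among them, at least 5 genes passed, and the highest of the other splits gave 4787. Since the splits are no measure of chance here, they speak neither for nor against it, and chance stays open for the fit without a block.

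By list, 13 lists differed for B. subtilis and 15 for E. faecium between the presence and absence of poly I:C. The cytokine and NF-kB lists were lower in both interactions, which compare log2 fold changes. A value below 0 thus means a smaller fold change by the bacterium with poly I:C, and does not by itself mean a lower level. TNF, for example, was at 785 ± 1040 CPM with E. faecium, 1360 ± 377 with poly I:C and 2510 ± 619 with both. With an estimated correlation 0 and 1 of these lists held, the latter being chemokines. For single genes in the E. faecium interaction 100 of 100 splits gave as many as the real 0 genes, which any splits would, so that this share says nothing. There were 95 genes at an unadjusted p under 0.05 with edgeR and 0 calls with DESeq2, and the highest of the other splits was also 0. No technical explanation was tested for the interactions beyond these settings.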

How the results depend on the processing

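The fits with library sets as a block, those without 2 named libraries and the tests of poly I:C against B. subtilis were chosen after seeing the data; all other tests here were planned. At the depth and spread of these libraries, with 3 per treatment, edgeR called 12% of changes of 1 log2 unit and 74% of changes of 2 on simulated data, and other depths were not tried. In no alternative did a named gene that passed pass in the other direction. RLE size factors, no filter on low counts and the filter at 50 counts in 3 libraries left the counts of genes within 1.5 times the reported ones in every comparison, except the interaction of B. subtilis and poly I:C, which went from 5 to 1 with RLE. RLE in place of TMM moved the median of all genes by at most 0.04 log2 units. Unless said otherwise the cause of a change was not tested.

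With the pig number as a block in edgeR the interaction of B. subtilis and poly I:C went from 5 genes to 0, and no other count left that range; for poly I:C against control it was 2929. DESeq2 called 1151 genes for B. subtilis against control, 38 for E. faecium against control, 28 for B. subtilis and poly I:C against poly I:C, 276 for B. subtilis against E. faecium, 595 for the combined treatments against each other, 115 for the interaction of B. subtilis and 1871 for poly I:C against B. subtilis. DESeq2 with the pig number as a block called 1143, 29, 1, 278, 379, 108 and 1842 in the same order.

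With the library sets as a block edgeR and DESeq2 called 5668 and 6013 genes for poly I:C, and 2504 and 3003 for B. subtilis, against control. For E. faecium against control edgeR stayed at 0 (278 at an unadjusted p under 0.05 without a block) and DESeq2 called 114; for B. subtilis and poly I:C against poly I:C DESeq2 called 949. The counts were 7416 and 7688 for B. subtilis and poly I:C against control, 5811 and 6135 for E. faecium and poly I:C against control, 5624 and 6029 for B. subtilis and poly I:C against B. subtilis, 4744 and 5171 for E. faecium and poly I:C against E. faecium, 927 and 1361 for B. subtilis against E. faecium, 1157 and 2680 for the combined treatments against each other, 521 and 1183 for the interaction of B. subtilis and 3481 and 3947 for poly I:C against B. subtilis. For the interaction of E. faecium DESeq2 called 1. The block takes out a spread that the sets share, with a common dispersion of 0.146 without it and 0.0435 with it. The sets were found from this same spread, so that a fall was built in and is no separate evidence for them. On 7127 genes of chromosomes not used to find the sets, the count went from 1553 to 2912 for poly I:C and from 287 to 1309 for B. subtilis against control. The sets were the same there for 18 of 18 libraries. Deviations of whole libraries recur on all chromosomes, so that this rise is no independent check of the block.

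Fitted on its own libraries only, B. subtilis and poly I:C had 2718 genes against control and 329 against B. subtilis, B. subtilis against E. faecium had 0, and the interaction of B. subtilis had 14. Without B. subtilis and poly I:C libraries 1 and 3 the counts were 2179 against control, 349 against B. subtilis and 0 for the interaction; the lone library is then assumed to vary like the other treatments.

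Leaving out 1 library, or 1 pig number in every treatment, gave these lowest and highest counts. In control, poly I:C, and B. subtilis with poly I:C, the numbers follow the sets. Leaving out a number takes the same set from each of these. In the other 3 treatments the numbers run in another order. Leaving out a number can then take different sets from the treatments compared and leave them unbalanced. Poly I:C against control had 636 (without replicate 3) and 2563 (without control replicate 2), and 2014 without control replicate 3. B. subtilis against control had 0 (without replicate 3) and 456 (without control replicate 2), with 156 without control replicate 3, 214 without control replicate 1, 195 without B. subtilis replicate 2 and 269 without B. subtilis replicate 1. E. faecium against control had 0 and 36 (without E. faecium replicate 2), and B. subtilis and poly I:C against poly I:C 0 and 2087 (without replicate 2 of the combined treatment). Against control, B. subtilis and poly I:C had 1342 and 6191, and E. faecium and poly I:C 877 and 2755. Against its bacterium, B. subtilis and poly I:C had 2 (without replicate 3) and 4854 (without replicate 2 of the combined treatment), and E. faecium and poly I:C 146 (without replicate 3) and 1954. B. subtilis against E. faecium had 0 and 85, the combined treatments against each other 0 and 3316 (without B. subtilis and poly I:C replicate 2), the interaction of B. subtilis 0 and 514 (without that same library), and poly I:C against B. subtilis 1 and 1078. E. faecium and poly I:C against poly I:C had 0 throughout.

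For lists, an estimated correlation left 0 of 13 for poly I:C against control, where fry gave 21, 7 for B. subtilis against control, 7 for E. faecium against control, where fry gave 0, and 0 for both bacteria on top of poly I:C, where fry gave 0 as well; with the sets as a block B. subtilis on top of poly I:C had 13. Similarity of responses moved as follows. At a mean of at least 3 log2 CPM r was -0.412 for both bacteria on top of poly I:C, reversed from 0.111, and 0.338 for B. subtilis without and with poly I:C. With each pig number left out, r was 0.399 to 0.747 for both bacteria against control, 0.535 to 0.636 for B. subtilis and poly I:C, 0.159 to 0.599 for E. faecium and poly I:C, 0.19 to 0.247 for B. subtilis without and with poly I:C, and 0.0987 to 0.492 for E. faecium without and with poly I:C.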

Other observations

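The tests of the library sets, of their column order, of E. faecium replicate 2 and of ribosomal proteins with 1 library left out were chosen after the results were seen; those of scaling and of gene span were not. Poly I:C and B. subtilis shared calls, and differed in the size of the antiviral response: 267 genes rose and 167 fell with both, and 48 of 59 interferon-stimulated genes were higher with poly I:C in the direct contrast, itself chosen after the data were seen. With B. subtilis these genes had a median above the control library of the same set in all 3 sets, by 0.71, 0.46 and 1.18 log2 units. Part of the likeness between treatments comes from the control they share. Simulated treatments without effect gave a mean r of 0.492 with a shared control. The real r of 0.703 for both bacteria and 0.685 for B. subtilis and poly I:C lay above all 100 simulations (highest 0.528). Their covariances were 0.26 and 0.679, against a simulated mean of 0.132. The simulations drew genes and libraries independently and held no library sets. They thus leave out deviations that genes share within a library, and cannot exclude chance for the excess. Without the libraries numbered 1 the r for both bacteria was 0.399, that for B. subtilis and poly I:C was 0.535, and that for E. faecium and poly I:C went from 0.57 to 0.159; with 2 libraries per treatment, of differing sets, these values cannot be set against the simulated ones.

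The inflammatory lists were higher with E. faecium while no single gene passed, and this may come from 1 library that lacked the response. Against the control library of its own set, E. faecium replicate 2 had an NF-kB list median of 0.04 log2 units, against 1.31 in replicate 1 and 0.9 in replicate 3, and without it 36 genes passed with edgeR. Libraries of its set in other treatments had medians between 1.6 and 2.07, so that the set responded to other stimuli. This does not show that it could respond to E. faecium. With E. faecium on top of poly I:C, TNF was at 1870 against 1710 CPM in this set. It was at 2560 against 959 CPM in set A and 3110 against 1420 in set C. A weak response of the whole set to E. faecium thus stays open. A shift of all genes was ruled out as the cause, with the list at 0.87 and genes of like abundance at 0.09, a difference of 0.78. E. faecium replicate 2 lay close to the control library of its set, with a chi-square per degree of freedom of 14 between them. The other pairs of E. faecium and control in a set had 51.3 and 126. The lowest of 153 pairs, at 11, was poly I:C replicate 2 and E. faecium with poly I:C replicate 1, of that same set. The pair of these treatments in set C had 11.6. Counting error alone would give 1, so that E. faecium replicate 2 is not a copy of the control library. A second library of untreated cells is not excluded.

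Ribosomal proteins were higher with B. subtilis and poly I:C than with E. faecium and poly I:C, 72 of 72 at a median of 1.14 log2 units. The tables argue against library scaling, since genes of like abundance were at 0.05 and the difference was 1.09. They argue against gene span and abundance as the whole cause, since genes matched on both were at 0.46 and the difference was 0.68, although 0.46 could be the part due to it. They argue against 1 library alone, since the lowest median with 1 of the 6 libraries left out was 0.75, without B. subtilis and poly I:C replicate 1. The rise sat in 2 of the 3 sets: against the control library of the same set, the median was 1.59 and 1.39 in replicates 1 and 3 of B. subtilis and poly I:C, which also had the lowest TMM factors (0.664 and 0.719), against -0.06 and 0.08 in the E. faecium and poly I:C libraries of those sets, and 0.12 in replicate 2 against 0.04. RNA quality and library preparation stay open, as does an effect of the bacteria, for which no test was available.

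The 18 libraries deviated together in 3 sets of 6 and not by the pig numbers. Noise of single genes was ruled out, as sets found on odd chromosomes had a mean correlation of 0.623 on the others. Deviations of whole libraries would recur on all chromosomes, so that this does not exclude them. Total counts overlapped in 3 of 3 pairs of sets, but over all treatments pooled, which cannot rule out depth within treatments. Set A had the highest total in control (27.3 M). It had the lowest with poly I:C (17.5 M), B. subtilis (17.1 M), E. faecium (16.4 M), and B. subtilis and poly I:C (16.3 M). A part of depth thus stays open. That the pig numbers name the wrong animal in some treatments stays open: with sets found on odd chromosomes, 81 genes of the other chromosomes separated a set from the other 12 libraries by more than 1 log2 unit, against at most 34 in 100 random assignments, and 0 followed the pig numbers. A culture day or a preparation batch, which the labels do not give, would make the same sets, so that animal and batch cannot be told apart. When the columns of the deposited table are put back from a text sort (1, 10, 11 and so on) to number order, they form 3 runs of 6 with the treatments in 1 order, and 18 of 18 libraries fall in the run of their set, against at most 16 in 1000 random assignments. The numbers may thus have been given along the sorted columns.

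Other splits of the 6 libraries of a comparison number 10, too few for a share under 0.05. For genes, the real value and the highest of the other splits were 3055 and 0 for poly I:C against control, 604 and 0 for B. subtilis against control, 4834 and 0 and 3146 and 0 for the combined treatments against control, 2566 and 0 and 2153 and 0 for these against their bacterium, and 24 and 4 for B. subtilis against E. faecium; in each of these 1 split, the real one, gave as many. The real value and the highest other were both 0 with edgeR for E. faecium against control, for E. faecium and poly I:C against poly I:C and for the combined treatments against each other. All 10 splits then gave as many, as they must with a real value of 0, so that this share says nothing. At an unadjusted p under 0.05 the counts were 278, 38 and 2245, and DESeq2 called 38, 0 and 595. For B. subtilis and poly I:C against poly I:C, with a real value of 0 (1423 at an unadjusted p under 0.05; 28 with DESeq2), 1 split gave 4045 genes by setting poly I:C replicate 1 and replicates 1 and 3 of the combined treatment against the rest, which points to a structure of the samples. For lists, the real value and the highest other were 13 and 21 for poly I:C, 13 and 16 for B. subtilis and 16 and 19 for E. faecium against control, with 6, 5 and 2 of the splits at least as high as the real one, and 8 and 10 and 7 and 10 for B. subtilis and E. faecium on top of poly I:C, with 5 and 6 of the splits.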
